A study of Rattus norvegicus with 160 samples.

How the data were processed

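The data are 160 RNA sequencing libraries from 40 pregnant rats, 5 dams in each of 8 groups (corn oil vehicle and 7 doses of ketoconazole). Each dam gave an mRNA and a small RNA library of liver and of placenta. Group, dose, tissue, dam number and RNA integrity number (RIN) were taken from the sample labels. One liver mRNA library, mRNA_2081 at 6.3 mg/kg/day, carries a label with exposure ending on gestation day 21 where the others end on day 20, and it was kept in its group. Libraries are named by the start of their titles, the RNA class and the number of the dam (mRNA_2081), and M stands for the usual unit of sequencing depth in which totals are given.

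Per the labels' protocols, RNA was extracted with a mirVana kit and libraries were made with TruSeq stranded mRNA and TruSeq small RNA kits. The deposited values are raw counts per Ensembl rat gene ID and library, whole numbers without normalization. The submitters' processing notes name CASAVA 1.8, HISAT2, HTSeq 0.7.2, cutadapt, Bowtie2 and bedtools 2.17.0, with no role or order. The genome build, annotation release and strand setting are not given in the sources used here, so overlapping and antisense genes may share counts. Both tables list the same 32545 gene IDs. The small RNA table therefore counts gene features, and a feature may hold reads of a microRNA inside it. In small RNA, 254 tested liver features and 276 placental ones had counts within 2% of another feature, and these are uncertain.

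The files do not pair the IDs with names, and the reference gene table used here matched 0 of them (its 47357 entries carry 0 Ensembl IDs). The 26 gene lists and 14 microRNA lists planned before the data were examined, and the checks on marker genes, were therefore not run. The rule for named genes took the largest rises and falls in log2 fold change among called features with a mean log2 CPM of at least 1 (mRNA) or 3 (small RNA). Without names, 2 IDs in each direction were printed for 40 mg/kg/day in each dataset.

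Features were kept by edgeR's filterByExpr with the dose group (minimum count 10, minimum total 15), which left 13064, 15640, 5698 and 5898 features in liver mRNA, placenta mRNA, liver small RNA and placenta small RNA. Counts were scaled by TMM. All 40 libraries of a dataset entered one quasi-likelihood fit (glmQLFit, robust, edgeR 4.0.16 with limma 3.58.1 in R 4.3.3), with a contrast of each dose to vehicle, and a second fit gave the trend over the rank of the dose (0 to 7). p-values were adjusted by Benjamini-Hochberg within a contrast, and features with an adjusted p under 0.05 were called. Standard errors are the log2 fold change divided by the square root of the F statistic. Tissue by dose interactions used the libraries of both tissues at vehicle and 40 mg/kg/day, with TMM within tissue. CPM values are scaled by TMM, given as mean ± SD over dams.

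The dam number pairs the tissues of one animal. After removing group means, libraries of the same dam had a mean correlation of 0.0642 in mRNA (0.434 at most) and 0.00706 in small RNA, against -0.00109 and -0.00017 for other dams. The pairing rests on the animal, not on these correlations, and the dam was a planned block.

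For the interpolated response dose, features with a called trend and a fitted change of at least 1.5 fold at some dose were taken. Isotonic regression of the group means of log2 CPM (prior count 2) was read at 1 pooled within-group SD from vehicle, on the log10 dose scale. Dams were resampled 100 times within groups. That resampling proved biased toward low doses, so its range is not used as a confidence interval.

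The count tests were checked on simulated data made from the libraries' means and sizes, for 40 mg/kg/day against vehicle. Of features changed by 4 fold, 77.3%, 84.8%, 86.4% and 86.4% were recovered in the order given above, of those changed by 2 fold 41.8%, 61.2%, 31.3% and 43.3%, and of those changed by 1.5 fold 10.4%, 29.9%, 7.46% and 4.48%, among 12962, 15516, 4752 and 5287 features. Unchanged features called numbered 0, 7, 2 and 6. The features were drawn independently of each other, so these counts do not show how often variation shared between libraries gives false calls.

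Pairs of libraries within a group were compared by a chi-square of their counts, and none agreed within sampling noise (the smallest ratio to its degrees of freedom in mRNA was 29.9). Within a tissue and RNA class libraries correlated at 0.901 or more and between tissues at 0.862 or less. Alternatives planned before the data were examined were the DESeq2 Wald test (DESeq2 1.42.0), DESeq2 size factors, no filter, edgeR's legacy dispersion, leaving out libraries of RIN under 7 or not computed, limma voom with quality weights, a minimum change of 1.5 fold, a benchmark of 1.5 fold, a prior count of 0.5, the dam as a block and leaving out each library or dam. Added after seeing the data were RIN and an integrity score (500 genes in each direction) as covariates, thinning to equal depth, the depth class of liver small RNA, log2 of the total counts, the features called in both fits, the share of the 10 most abundant genes, single members of near-identical sets, and resampling with a fixed benchmark.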

Results

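Pregnant rats received the antifungal ketoconazole, an azole that blocks cytochrome P450 enzymes of sterol and steroid synthesis, in corn oil from gestation day 6 to day 20. Maternal liver and placenta were collected on gestation day 21. The vehicle group and 7 dose groups (0.063, 0.2, 0.63, 2, 6.3, 20 and 40 mg/kg/day) held 5 dams each. Each of the 40 dams gave 4 libraries, an mRNA and a small RNA library from each tissue, so 160 libraries were analysed. The doses were separate animals, and the spread between dams is the error behind every test. Total counts, in M as sequencing depth is usually given, ranged from 22.2 to 66.8 M in liver mRNA, from 17.6 to 58.6 M in placenta mRNA, from 9.02 to 25.4 M in liver small RNA and from 6.46 to 19.8 M in placenta small RNA. The question was at which dose each tissue and each class of RNA first departed from vehicle.

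Both classes of RNA were counted over Ensembl rat gene IDs. The files do not pair these IDs with gene names, so pathways and named genes, the microRNAs included, are not reported. For 40 mg/kg/day in each tissue and RNA class, the IDs given are the 2 largest rises and 2 largest falls under the ranking fixed in advance. A count in the small RNA table belongs to a gene feature, not to a mature microRNA. A called feature passed an adjusted p of 0.05 in edgeR's quasi-likelihood test against vehicle, with Benjamini-Hochberg adjustment.

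In the placenta, mRNA changes appeared at the top of the dose range. At 40 mg/kg/day 2414 of 15640 genes were called, 1272 higher and 1142 lower. At 20 mg/kg/day 462 genes were called, 247 higher and 215 lower. ENSRNOG00000019183 rose from 14.6 ± 5.62 CPM (SD, n = 5) in vehicle dams to 126 ± 79.1 CPM at 40 mg/kg/day, a log2 fold change of 3.11 (SE 0.52, adjusted p = 0.000191, edgeR), and all 5 treated dams lay above all vehicle dams. It was also higher at 20 mg/kg/day, by 2.08 on the log2 scale (SE 0.501, adjusted p = 0.0201). ENSRNOG00000011205 rose by 3.54 (SE 0.735, adjusted p = 0.00164), with 3 of the 5 treated dams above all vehicle dams and library mRNA_2101 at 108 CPM. Without that library the log2 fold change was 2.05, and with limma voom it was 2.19 (adjusted p = 0.0217 and 0.0401, where the alternatives ranged from 3.02e-05 to 0.0401). ENSRNOG00000029945 fell from 9.19 ± 5.67 to 0.561 ± 0.614 CPM (log2 fold change -4.20, SE 1.09, adjusted p = 0.0089). ENSRNOG00000014940 fell from 14.8 ± 8.57 to 0.959 ± 0.578 CPM (log2 fold change -4.02, SE 1.04, adjusted p = 0.00889). For both, all 5 treated dams lay below all vehicle dams. With limma voom ENSRNOG00000029945 had a log2 fold change of -3.90 and missed the threshold (adjusted p = 0.065, with 0.00049 to 0.065 over the alternatives), and without treated library mRNA_2099 it was at -5.04. A trend over the ranked doses was called for 2698 genes, 1553 rising and 1145 falling.

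**Figure D1:**
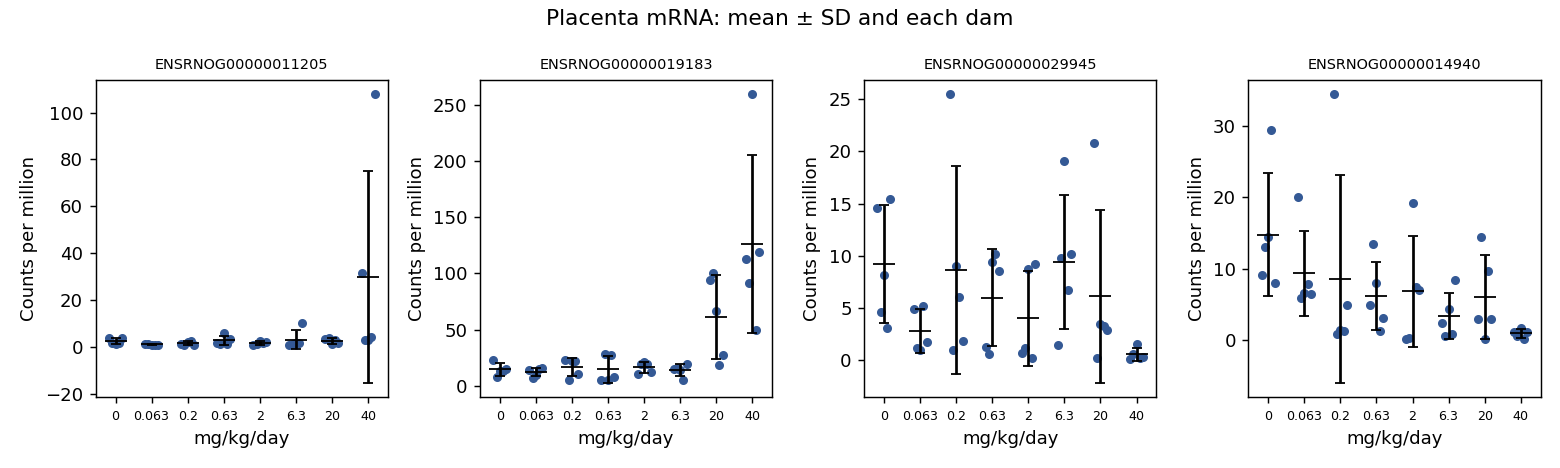
CPM (linear axis) of 4 gene IDs in placenta mRNA by dose of ketoconazole; points are the 5 dams of a group, the horizontal mark is the mean and the bar 1 SD. ENSRNOG00000019183 averages 14.6 CPM in vehicle dams and 126 CPM at 40 mg/kg/day, while ENSRNOG00000014940 averages 14.8 and 0.959 CPM.

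Below 20 mg/kg/day edgeR called 2 placental genes over the 5 lower doses, 1 at 0.063 and 1 at 0.2 mg/kg/day. At these doses 2283 and 2476 genes had an unadjusted p under 0.05, where chance gives 782. At 0.63, 2 and 6.3 mg/kg/day edgeR called 0, with 283, 1544 and 1138 genes at an unadjusted p under 0.05. Leaving out 1 library moved the 2 calls to between 1 and 73, with 73 without mRNA_2044 at 0.2 mg/kg/day and 12, 14, 21 and 16 without vehicle libraries mRNA_2026, mRNA_2027, mRNA_2030 and mRNA_2032. The number at low doses also depended on the test. The DESeq2 Wald test called 9, 40, 0, 0 and 39 genes from 0.063 to 6.3 mg/kg/day, and limma voom with quality weights called 581, 2023, 0, 0 and 240. The count at 20 mg/kg/day fell to 176 without vehicle library mRNA_2025, 284 without vehicle library mRNA_2027, 246 without treated library mRNA_2084 and 231 without treated library mRNA_2091.

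In the liver, edgeR's mRNA calls lay at 6.3 mg/kg/day and above, and their number was lower at 20 and 40 mg/kg/day than at 6.3. An alternative added after seeing the data took an integrity score made from expression as a covariate. The order of the counts then turned round, with 93, 376 and 675 genes called at 6.3, 20 and 40 mg/kg/day. The score was set by libraries of RIN under 7 or not computed against the others, and it follows RIN only in part. It was highest in mRNA_2101 (RIN 2.6), at 6.106. In mRNA_2044 (RIN 2) it was 2.543. In mRNA_2087 at 20 mg/kg/day (RIN 8) it was 3.832, above vehicle library mRNA_2032 (RIN 5.1) at 3.666. Over libraries of RIN 7 or more the same score gave 600, 4 and 23. Of those 600 genes, 102 were among the 3162 called at 6.3 mg/kg/day with all libraries and no covariate. Only 68 of the 102 kept their direction, so the 600 are mostly other genes. At 6.3 mg/kg/day 3162 of 13064 genes were called (1223 higher, 1939 lower), at 20 mg/kg/day 2613 (1255 higher, 1358 lower) and at 40 mg/kg/day 1136 (766 higher, 370 lower). At 0.063, 0.2, 0.63 and 2 mg/kg/day edgeR called 0 genes, with 364, 266, 365 and 521 at an unadjusted p under 0.05. DESeq2 called 2, 0, 0 and 0 at these doses and limma voom 0 at each. ENSRNOG00000043098 rose from 1.89 ± 1.92 CPM (SD, n = 5) to 664 ± 1050 CPM at 40 mg/kg/day (log2 fold change 8.46, SE 1.61, adjusted p = 0.00226), above all vehicle dams in 5 of 5. Low-integrity library mRNA_2101 was at 2426 CPM and mRNA_2094 at 839 CPM, with the other 3 dams between 8.26 and 37.6 CPM. Without mRNA_2101 the log2 fold change was 6.89, and without vehicle library mRNA_2032 it was 9.33. The log2 fold change of this ID was 4.22 with limma voom (adjusted p = 0.0375) and as low as 2.62 with an integrity score as a covariate over RIN of 7 or more (adjusted p = 0.316, the highest of its alternatives, which started at 3.82e-10). ENSRNOG00000013973 rose by 7.67 (SE 1.24, adjusted p = 0.000608), but 2 of 5 dams lay above all vehicle dams, 1 of them mRNA_2101 at 7280 CPM, and limma voom gave a log2 fold change of 0.09 (adjusted p = 0.939, with 3.98e-13 to 0.939 over the alternatives). Without mRNA_2101 it was 5.13. ENSRNOG00000020035 fell from 28.3 ± 23.1 to 2.95 ± 1.65 CPM (log2 fold change -3.25, SE 0.665, adjusted p = 0.00385, and -2.63 without vehicle library mRNA_2026). ENSRNOG00000056322 fell from 3.99 ± 0.915 to 0.857 ± 0.871 CPM (log2 fold change -2.18, SE 0.503, adjusted p = 0.00807). Both were below all vehicle dams in 5 of 5. With the integrity score as a covariate over RIN of 7 or more, their log2 fold changes were -2.615 and -1.404 (adjusted p = 0.179 for each, edgeR). In that fit ENSRNOG00000013973 was at 1.566 (adjusted p = 0.734). A dose trend was called for 6407 genes.

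The liver libraries also differed in RNA integrity. The RNA integrity number (RIN) was under 7 or not computed in 1 dam each of vehicle and 0.2, 6.3, 20 and 40 mg/kg/day. Among the other dams its mean was 8.83 ± 0.25 in vehicle, 8.15 ± 0.238 at 6.3, 8.13 ± 0.377 at 20 and 8.50 ± 0.271 at 40 mg/kg/day. Without the libraries of low or missing RIN, 4915, 4667 and 1404 genes were called at 6.3, 20 and 40 mg/kg/day, and 2945, 2382 and 752 of these were also called with all libraries. With RIN as a covariate over these remaining libraries, 1928, 718 and 135 genes were called. None of the 4 liver IDs passed the threshold in that fit, with adjusted p-values from edgeR between 0.0524 and 0.0555. The genes called with all libraries had median log2 changes of 1.02, 1.01 and 0.833 over the remaining libraries (median SE 0.236, 0.247 and 0.258), and of 0.79, 0.748 and 0.721 with the covariate (median SE 0.275, 0.294 and 0.267). With the integrity score as the covariate these medians were 0.29, 0.431 and 0.689 over all libraries and 0.091, 0.131 and 0.426 over the remaining ones. Over the remaining libraries RIN as a covariate took the log2 fold change of ENSRNOG00000043098 from 7.77 (SE 1.67) to 5.59 (SE 1.45), of ENSRNOG00000013973 from 5.13 (SE 1.15) to 4.75 (SE 1.27), of ENSRNOG00000020035 from -3.02 (SE 0.741) to -2.96 (SE 0.776) and of ENSRNOG00000056322 from -1.98 (SE 0.459) to -1.83 (SE 0.483). With RIN as a covariate over all libraries with a RIN, all 4 passed the threshold (adjusted p from 0.00276 to 0.00438). Single libraries moved the counts as well. The 40 mg/kg/day count was 344 without treated library mRNA_2101, 353 without mRNA_2094, 1966 without mRNA_2097 and 2420 without mRNA_2100, and it was 647, 618, 523 and 2623 without vehicle libraries mRNA_2025, mRNA_2026, mRNA_2027 and mRNA_2032. The 20 mg/kg/day count was 724 without treated library mRNA_2092, 823 without mRNA_2087, and 1412, 1654, 1688, 1356 and 4439 without vehicle libraries mRNA_2025, mRNA_2026, mRNA_2027, mRNA_2030 and mRNA_2032. The lower-dose count of 3162 was 1408 without treated library mRNA_2081, and 1838, 1618 and 4988 without vehicle libraries mRNA_2025, mRNA_2030 and mRNA_2032.

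**Figure D2:**
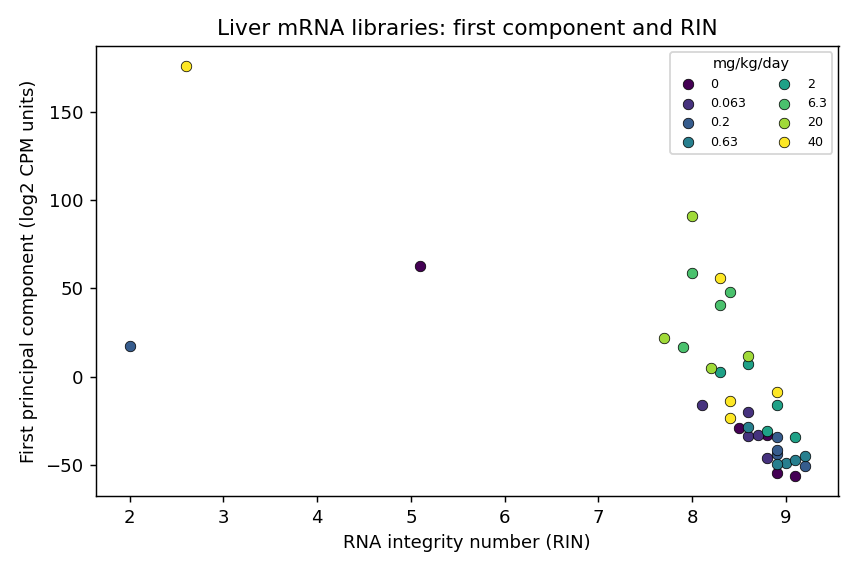
First principal component of log2 CPM against RIN for the liver mRNA libraries with a computed RIN, 1 point per dam, coloured by dose in mg/kg/day. The component carries 44.4% of the variance, and the 40 mg/kg/day library with a RIN of 2.6 lies at its upper end. The 0.2 mg/kg/day library with a RIN of 2 lies at 17.3, below library mRNA_2087 at 20 mg/kg/day with a RIN of 8, at 91.4.

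**Figure D3:**
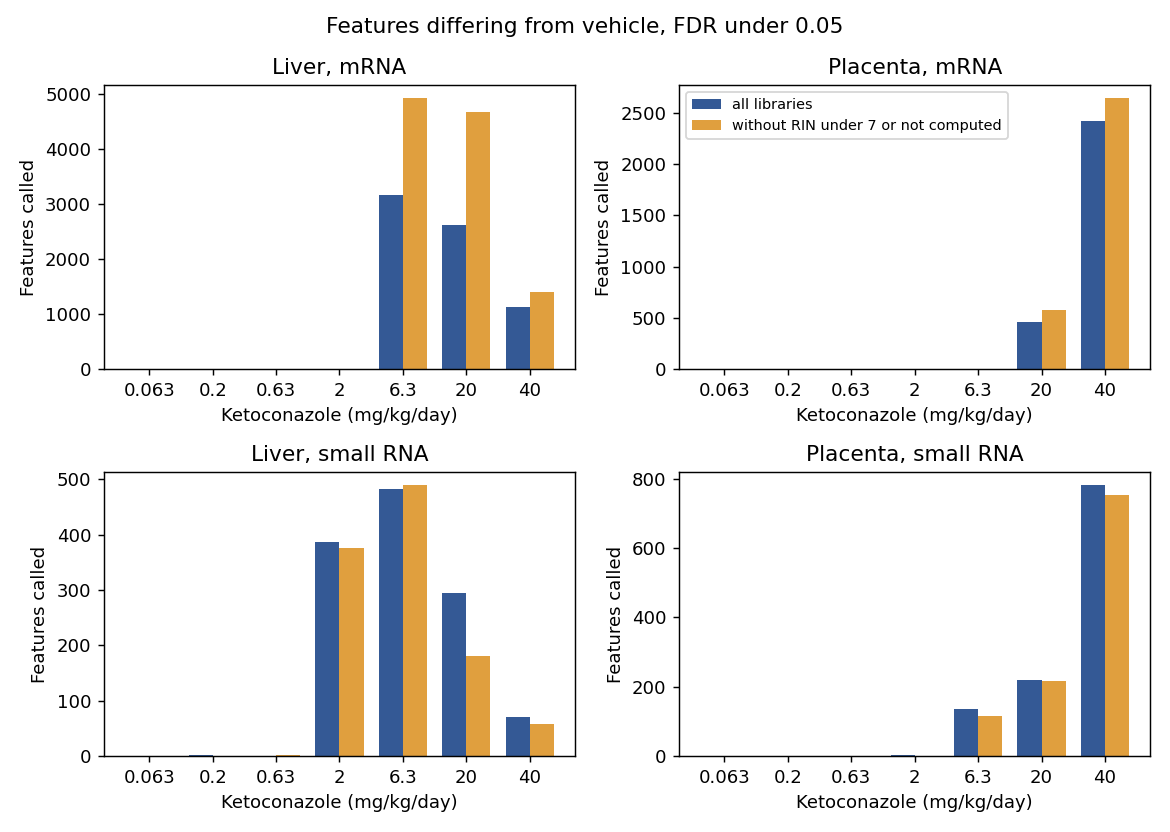
Features called against vehicle (adjusted p under 0.05) by dose in the 4 datasets, with all libraries and without those of RIN under 7 or not computed. Placenta mRNA calls rise from 462 at 20 to 2414 at 40 mg/kg/day, while liver mRNA calls go from 3162 at 6.3 to 1136 at 40 mg/kg/day.

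Most placental small RNA calls lay at 6.3 mg/kg/day and above. Of 5898 features, 136 were called at 6.3 mg/kg/day (30 higher, 106 lower; 7 and 82 with DESeq2 size factors), 221 at 20 (150 higher, 71 lower) and 781 at 40 (414 higher, 367 lower). At 0.063 and 0.2 mg/kg/day edgeR, DESeq2 and limma voom called 0 features each, with 195 and 245 at an unadjusted p under 0.05 in edgeR. At 0.63 and 2 mg/kg/day edgeR called 2 and 3 features, the DESeq2 Wald test 3 and 24, and limma voom 0 and 8. ENSRNOG00000052998 rose from 8.32 ± 1.47 CPM (SD, n = 5) to 102 ± 121 CPM at 40 mg/kg/day (log2 fold change 3.62, SE 0.667, adjusted p = 0.000508) and to 140 ± 146 CPM at 20 mg/kg/day. Without treated library microRNA_2094, at 313 CPM, the log2 fold change at 40 mg/kg/day was 2.56 (adjusted p = 0.00611, with 1.23e-06 to 0.00611 over the alternatives). ENSRNOG00000046081 had near-identical counts, so the values of both are uncertain. ENSRNOG00000058132, the most abundant of those named here, fell from 18680 ± 11300 to 5701 ± 1190 CPM (log2 fold change -1.71, SE 0.33, adjusted p = 0.000559), below all vehicle dams in 5 of 5. ENSRNOG00000060578 fell (log2 fold change -1.80, SE 0.478, adjusted p = 0.01), below all vehicle dams in 4 of 5, and its call was lost without vehicle library microRNA_2027 (adjusted p = 0.0647, with 0.000459 to 0.0647 over the alternatives). Total counts differed between these groups as well, from 8.37 to 11.5 M in vehicle, 7.94 to 8.99 M at 6.3, 7.07 to 19.8 M at 20 and 6.46 to 8.54 M at 40 mg/kg/day. At 20 mg/kg/day ENSRNOG00000058132 was at 10979 and 20271 CPM in the deepest libraries, microRNA_2087 and microRNA_2091, and at 5500 to 7072 CPM in the other 3, and ENSRNOG00000060578 was at 93.1 and 158 CPM against 18.2 to 26.9 CPM. With log2 of the total counts as a covariate, an alternative added after seeing the data, 136, 286 and 552 features were called at 6.3, 20 and 40 mg/kg/day, and 115, 213 and 531 of these were also called without it, all in the same direction. In that fit the log2 fold changes at 40 mg/kg/day were -1.50 for ENSRNOG00000058132 (SE 0.344, adjusted p = 0.00564) and -1.43 for ENSRNOG00000060578 (SE 0.466, adjusted p = 0.0484). The median log2 fold change of all features at 40 mg/kg/day was 0.17, and 0.07 with DESeq2 size factors. With those factors 696 features were called, 291 higher and 405 lower, so the share of higher calls went from 53% to 41.8%. A dose trend was called for 1237 features (65.7% rising, 54.9% with DESeq2 size factors). Without treated library microRNA_2094 the count at 40 mg/kg/day was 375 and the trend count 737. The count at 20 mg/kg/day was 80 without treated library microRNA_2086, 335 without microRNA_2087, and 141 and 127 without vehicle libraries microRNA_2025 and microRNA_2026. The lower-dose count of 137 was 49, 65 and 20 without treated libraries microRNA_2074, microRNA_2079 and microRNA_2081, and 53 and 26 without vehicle libraries microRNA_2025 and microRNA_2027.

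Most liver small RNA calls lay at 2 mg/kg/day and above. Of 5698 features, 387 were called at 2 mg/kg/day (126 higher, 261 lower; 74 and 286 with DESeq2 size factors), 483 at 6.3 (216 higher, 267 lower), 294 at 20 (156 higher, 138 lower) and 71 at 40 (39 higher, 32 lower). At 0.063 mg/kg/day edgeR, DESeq2 and limma voom called 0, with 277 features at an unadjusted p under 0.05 in edgeR. At 0.2 and 0.63 mg/kg/day edgeR called 2 and 1 features, the DESeq2 Wald test 6 and 1, and limma voom 7 and 1. ENSRNOG00000035451 rose from 32.6 ± 8.67 to 80.2 ± 17 CPM at 40 mg/kg/day (log2 fold change 1.30, SE 0.255, adjusted p = 0.00636). ENSRNOG00000058488 rose from 125 ± 14.7 to 346 ± 89.8 CPM (log2 fold change 1.46, SE 0.375, adjusted p = 0.0379), but at 6.3 mg/kg/day it was lower than in vehicle (log2 fold change -1.47, adjusted p = 0.00783). At 6.3 mg/kg/day the 4 libraries under 12 M counts were at 26.8 to 46.4 CPM and the other at 77.7 CPM, and at 20 mg/kg/day the 2 libraries under 12 M were at 36.3 and 44.1 CPM and the other 3 at 238 to 286 CPM. Its call at 40 was lost whichever of the 10 libraries was left out, with a log2 fold change between 1.31 and 1.58. Over all its alternatives the adjusted p ran from 3.47e-05 (libraries over 12 M counts) to 0.132. ENSRNOG00000053668 fell by 1.19 on the log2 scale (SE 0.245, adjusted p = 0.011), with the call lost without vehicle library microRNA_2025 or treated library microRNA_2094 (adjusted p = 0.0595 and 0.0638, with 0.000134 to 0.0638 over the alternatives). ENSRNOG00000053973 fell by 1.10 (SE 0.289, adjusted p = 0.0402), and by 2.70 at 6.3 mg/kg/day (adjusted p = 3.07e-08). Its call at 40 was lost in 9 of the 10 fits without 1 library, and held without treated library microRNA_2100. Over all its alternatives the adjusted p ran from 0.000782 to 0.176, and 11 of 21 missed the threshold. A dose trend was called for 576 features. The count at 40 mg/kg/day was 6, 38 and 14 without vehicle libraries microRNA_2025, microRNA_2027 and microRNA_2030, and 7 and 120 without treated libraries microRNA_2094 and microRNA_2100. The count at 20 mg/kg/day was 163 and 194 without vehicle libraries microRNA_2025 and microRNA_2030, and 189 and 158 without treated libraries microRNA_2087 and microRNA_2092.

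Total counts of these libraries did not follow dose evenly. Under 12 M counts were found in all 5 libraries at 2 mg/kg/day, 4 at 6.3, 2 at 20, 1 at 0.2 and 0 in vehicle. The limit of 12 M was set after the totals had been seen, and the totals have no clear break there, with a gap from 11.6 to 13.1 M and a wider one from 13.1 to 14.6 M. With this class as a covariate, 63, 343, 336 and 144 features were called at 2, 6.3, 20 and 40 mg/kg/day. With log2 of the total counts as a covariate, which needs no limit, 29, 162, 180 and 111 were called. Among libraries over 12 M counts there was no library at 2 mg/kg/day, and 101 features were called at 6.3, 283 at 20 and 121 at 40. The 6.3 mg/kg/day group then held 1 library, which the fit assumes to vary like the other groups. At 2 mg/kg/day the dose and the depth class cannot be told apart within the libraries of that group and vehicle.

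**Figure D4:**
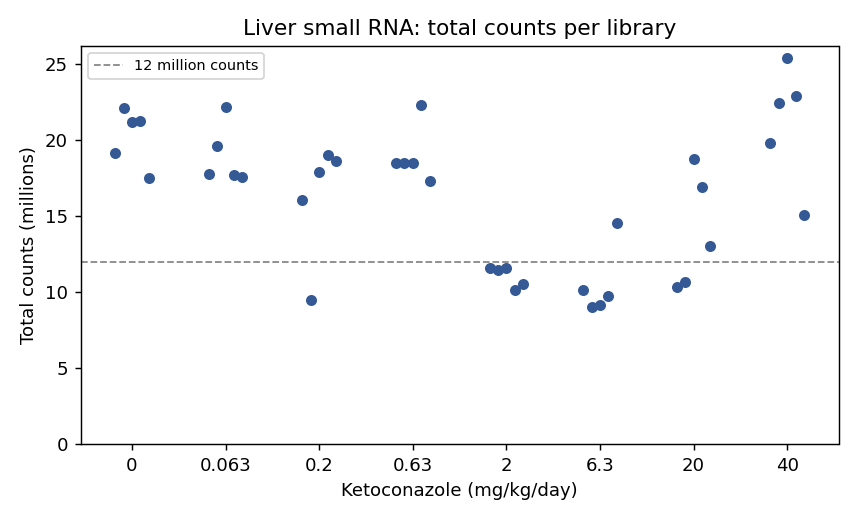
Total counts in M of each liver small RNA library by dose, 1 point per dam, with a dashed line at 12 M. All 5 libraries at 2 mg/kg/day lie between 10.2 and 11.6 M, and all vehicle libraries between 17.5 and 22.1 M.

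Whether the tissues responded differently at 40 mg/kg/day was tested as a tissue by dose interaction. Of 11640 genes, 134 had a different mRNA change in placenta than in liver, with the placental change higher for 48 and lower for 86. With the dam as a replicate block, which pairs the tissues of an animal, 5 genes were called, 3 of them in both fits. Without both dams of low RIN 497 genes were called, and without single dams the count fell as far as 3 (the vehicle dam of mRNA_2027), with 14, 11 and 63 without the vehicle dams of mRNA_2025, mRNA_2026 and mRNA_2030 and 19 and 33 without the treated dams of mRNA_2094 and mRNA_2099. In small RNA 230 of 2487 features were called, and 217 with the dam as a replicate block, 199 of them in both fits. ENSRNOG00000052998 differed by 3.93 on the log2 scale, higher in placenta (adjusted p = 0.00196, edgeR). Across the 12588 genes tested in both tissues, the fold changes at 40 mg/kg/day had a Pearson correlation of 0.0782, where genes are not independent replicates, and 200 genes were called in both against 168.1 for independent lists. Of the 200, 112 changed in the same direction and 88 in opposite ones, against 86.2 and 81.9 for independent lists. In small RNA 17 features were called in both, 9 in the same direction and 8 in opposite ones, against 4.15 and 4.24.

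The calls at 20 and 40 mg/kg/day in one dataset share their vehicle libraries. In placenta mRNA 407 genes were called at both doses, all 407 in the same direction, against 35.8 for independent lists. Unchanged groups simulated against shared controls gave a mean of 0, but genes without any change are rarely called at either dose. That count therefore cannot show how much overlap the shared controls add. With the vehicle dams split between the comparisons a median of 57 were called at both. Each comparison then has fewer vehicle dams, which lowers the number of calls, so this drop does not measure the shared controls alone. The covariance of the fold changes, which does not rest on calls, was 0.246, with a median of 0.155 after the split and 0.0529 in the simulation. In liver mRNA 634 genes were called at both, against 112 for independent lists, with a simulated mean of 0.05 under the same limit. After splitting vehicle the median was 11. The covariance was 0.434 (median 0.361 after the split, 0.0947 simulated). In small RNA 166 placental features (14.9 for independent lists) and 41 liver features (1.84) were called at both, with medians of 19.5 and 1 after the split. Their covariances were 0.324 (median 0.266 after the split, 0.0685 simulated) and 0.179 (median 0.119 after the split, 0.0679 simulated).

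For features with a dose trend and a change of at least 1.5 fold, the dose at which the fitted curve first departed from vehicle by 1 SD was interpolated. The median was 3.64 mg/kg/day over 4875 genes in liver mRNA, 7.08 over 1262 in placenta mRNA, 1.45 over 519 features in liver small RNA and 9.35 over 1079 in placenta small RNA. Without libraries of low or missing RIN the median was 2.04 in liver mRNA, and with a benchmark of 1.5 fold in place of 1 SD it was 10.8 in placenta mRNA and 3.35 in liver small RNA. No confidence interval is given for these doses. The 100 resamples of dams planned for that purpose came out lower than the estimate, with middle values of 3.18, 3.24, 1.09 and 7.33 mg/kg/day. Drawing dams with replacement made the SD benchmark smaller (0.922, 0.895, 0.891 and 0.9 of its value). The central 95% of resamples ran from 1.66 to 4.49, 1.22 to 6.80, 0.66 to 1.56 and 2.94 to 9.09 mg/kg/day, and 2 of these ranges exclude the estimate itself. Holding the benchmark at its full value, a choice made after seeing this, gave 2.52 to 4.75, 2.29 to 7.91, 0.905 to 1.79 and 6.73 to 10.4 mg/kg/day. The middle values were then 3.54, 5.03, 1.31 and 8.3 mg/kg/day, still below the estimates, and what else lowers them was not tested. The 10th percentiles were 1.92, 0.059, 0.139 and 0.449 mg/kg/day, and that of placenta mRNA lies below the lowest dose given. Without 1 vehicle library the 10th percentile was 1.25 in liver mRNA (mRNA_2032), 0.0683 in liver small RNA (microRNA_2026) and 0.252 in placenta small RNA (microRNA_2030). On simulated curves with a true dose of 2.82 mg/kg/day the median estimate was 2.51. These curves rose steeply in a known direction and were not selected by a trend. They therefore cannot show the bias for the features measured here. Of features simulated without any change, 8.2% were given a dose. The liver values carry the differences in RNA integrity and total counts given above. Differences between datasets in these doses were not tested.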

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

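Tests of RIN and of the integrity score as covariates and against the low-integrity change, of the depth class as a covariate and of the features called in both fits were chosen after the counts had been seen, as were the splits restricted to libraries of RIN 7 or more. Leaving out libraries of low or missing RIN was a planned setting, and what it would show was written down after its counts had been seen. Thinning, log2 of the total counts as a covariate, the transfer of the class difference from other doses and the abundant-gene share were added after seeing the data, and what they and the other splits would show was written down before their results were seen.

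The number of liver mRNA calls falls from 6.3 to 40 mg/kg/day, but rises with an integrity score made from expression as a covariate (93, 376 and 675 calls at 6.3, 20 and 40, though 600, 4 and 23 over libraries of RIN 7 or more), and the liver libraries differ in RNA integrity. Of those 600 genes, 102 were among the 3162 called with all libraries and no covariate, 68 of them in the same direction. At 6.3 and 20 mg/kg/day the libraries of low or missing RIN alone are argued against. Without them 4915 and 4667 genes were called, with 2945 and 2382 of them among the 3162 and 2613 of all libraries. At 40 mg/kg/day they are argued against only as the cause of all calls, with 1404 genes called without them and 752 of these among the 1136. Without only the treated library of low or missing RIN, 1408 genes were called at the lower doses, 724 at 20 and 344 at 40 mg/kg/day. Without only vehicle library mRNA_2032 the counts were 4988, 4439 and 2623. Thinning gave 3118, 2623 and 1143 calls at 6.3, 20 and 40 mg/kg/day, and 2901, 2404 and 1013 of these were also called with the full counts. This argues against the number of counts sampled. With log2 of the total counts as a covariate 3699, 3193 and 939 genes were called, 2988, 2448 and 687 of them also without it. All totals at 40 mg/kg/day (42.4 to 53 M) lay above those of vehicle (22.2 to 36.5 M). What else goes with the total therefore cannot be told apart from the dose at 40 mg/kg/day. A graded difference in integrity stays open: among libraries of RIN 7 or more, the change at these doses correlated across genes, which are not independent replicates, with the low-integrity change measured in other dose groups, at 0.753, 0.714 and 0.549, against 0.305, 0.0587, 0.00609 and 0.524 at 0.063, 0.2, 0.63 and 2 mg/kg/day. RIN as a covariate gave 3096, 2648 and 1490 calls over all libraries with a RIN and 1928, 718 and 135 over those of RIN 7 or more, where the median log2 change of the genes called with all libraries went from 1.02, 1.01 and 0.833 (median SE 0.236, 0.247 and 0.258) to 0.79, 0.748 and 0.721 (median SE 0.275, 0.294 and 0.267), against 0.091, 0.131 and 0.426 under the score over the same libraries and 0.29, 0.431 and 0.689 under it over all libraries. Integrity and a response to the dose cannot be told apart here, because RIN is lower in the 6.3 and 20 mg/kg/day groups and the score also removes any response to dose in its genes. The score also follows RIN only in part.

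Chance cannot be excluded for the liver mRNA count at 40 mg/kg/day over all libraries: 15 of 100 splits of the 10 libraries called at least the real 1136 genes, and the highest other split called 4273, with both low-RIN libraries on the same side. Several times the real count points to a structure of the samples, whose source these splits do not show. Over libraries of RIN 7 or more, 1 of 35 splits reached the real 1404 and the highest other called 8. At 20 mg/kg/day 4 of 100 splits reached the real 2613 (highest other 4703, again with both low-RIN libraries together), and 1 of 35 reached 4667 over libraries of RIN 7 or more (highest other 1696, with no library of low RIN present). For the lower doses 2 of 100 reached 3162 (highest other 4279), and for the trend 1 of 100 reached 6407 (highest other 320).

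Liver small RNA calls at 2 mg/kg/day coincide with libraries of under 12 M counts, a limit set after the totals had been seen. Thinning gave 393 calls at 2 and 477 at 6.3 mg/kg/day, 323 and 409 of them among the 387 and 483 of the full counts, which argues against the number of counts sampled. The class as a covariate gave 63 calls at 2 and 343 at 6.3 mg/kg/day, but log2 of the total counts gave 29 and 162 and took the median log2 change of the called features from 1.23 to 0.736 (median SE 0.275 to 0.323) and from 1.19 to 0.811 (0.273 to 0.338), so what goes with the total may account for many calls at both doses, while a step at 12 M is argued against as the whole cause at 6.3. Within 0.2, 6.3 and 20 mg/kg/day, the 387 features differed between the classes in the direction of the call by a median of 0.544 against a change of 1.12 at 2 mg/kg/day, a ratio of 0.484 (0.407 to 0.567 without each group), which lies just under the 0.5 set beforehand. Class and dose cannot be told apart at 2 mg/kg/day, where all 5 libraries are of the low class and 0 vehicle libraries are.

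The placental mRNA calls at 40 mg/kg/day were set against RIN, depth and the share of counts in the 10 most abundant genes. RIN as a covariate gave 2669 calls, thinning 2050, log2 of the total counts as a covariate 2185 and the share of the 10 most abundant genes as a covariate 2390, against 2414, and 2349, 1920, 2106 and 1862 of these were among the 2414, all in the same direction. The median log2 change of the 2414 genes was 0.655, with 0.652 under the RIN covariate, 0.647 under the total and 0.601 under the share, and that of the 2331 still tested after thinning was 0.627 against 0.633. The lowest placental RIN, 6 in library mRNA_2069, lies at 2 mg/kg/day and thus outside this contrast. Over libraries of RIN 7 or more, RIN as a covariate gave 2562 calls, 1997 of them among the 2414 and in the same direction. The median log2 change of the 2414 genes was then 0.657. These values argue against RIN, depth and that share as the cause of most calls. A response to the dose remains a hypothesis, found and tested on the same data. The mix of cell types and other differences between the groups were not tested.

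In the other splits, chance was argued against for placenta mRNA at 40 mg/kg/day (1 of 100 reached 2414, highest other 553), at 20 (1 of 100 reached 462, highest other 33) and for its trend (1 of 100 reached 2698, highest other 39). It was not argued against for the 2 placental genes at the lower doses (8 of 100, highest other 254). It was argued against for placental small RNA at 40 (1 of 100 reached 781, highest other 347), at the lower doses (1 of 100 reached 137, highest other 25) and for the trend (1 of 100 reached 1237, highest other 205). It was argued against for liver small RNA at 20 (1 of 100 reached 294, highest other 58), at the lower doses (1 of 100 reached 591, highest other 146) and for the trend (1 of 100 reached 576, highest other 1). For 2 counts another split called more than the real grouping. They are placental small RNA at 20 (2 of 100 reached 221, highest other 258) and liver small RNA at 40 (2 of 100 reached 71, highest other 76, with both low-RIN libraries on the same side). Chance is unlikely but not excluded for these, as many counts were tested by splits.

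By the interaction test without the dam in the fit, the effect at 40 mg/kg/day differed between liver and placenta for 134 genes and 230 small RNA features. In that fit 1 of 100 splits of the dams was as large in each (highest other 15 and 26). With the dam as a replicate block the counts were 5 and 217, and no splits were run with it. Placental small RNA totals were 6.46 to 8.54 M at 40 mg/kg/day and 8.37 to 11.5 M in vehicle. Total counts were not tested in the interaction.

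Total counts, RIN and the CPM of the printed IDs were checked within dose groups. Of 80 such checks, 13 found a library far from the other dams. Chance flags about 5% where values are independent and normally spread. That rate does not hold for the printed IDs, which were picked for large changes at 40 mg/kg/day. Of these IDs, ENSRNOG00000052998 and ENSRNOG00000046081 also have near-identical counts. The RIN of liver was 5.1 in vehicle library mRNA_2032 (others 8.5 to 9.1), 8.1 in library mRNA_2040 at 0.063 mg/kg/day (8.6 to 8.8), 2 in library mRNA_2044 at 0.2 (8.9 to 9.2) and 2.6 in library mRNA_2101 at 40 (8.3 to 8.9), and that of placenta was 6 in library mRNA_2069 at 2 (9 to 9.5). ENSRNOG00000043098 in liver mRNA was at 5.29 CPM in vehicle library mRNA_2032 (others 0.635 to 1.48), and ENSRNOG00000013973 at 7280 CPM in library mRNA_2101 at 40 mg/kg/day (4.4 to 1140). ENSRNOG00000011205 in placenta mRNA was at 108 CPM in library mRNA_2101 at 40 mg/kg/day (2.85 to 31.6). In placental small RNA, ENSRNOG00000052998 and ENSRNOG00000046081 were at 313 and 314 CPM in library microRNA_2094 at 40 mg/kg/day (13 to 89.2 and 11.8 to 92.1 in the others). Liver small RNA totals were 22.3 M in library microRNA_2062 at 0.63 (17.3 to 18.5) and 14.6 M in library microRNA_2081 at 6.3 (9.02 to 10.1), and the placental total was 9.19 M in library microRNA_2062 at 0.63 mg/kg/day (10.3 to 10.6).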

How the results depend on the processing

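RIN and integrity-score covariates, thinning, depth class, log2 of the total counts, abundant-gene share and single members of near-identical sets were chosen after seeing the data; the others were planned. The planned gene and microRNA lists were not run, since the IDs carry no names. No fold change of a printed ID changed sign under any setting run, but counts often moved by over 1.5 times, and where no value is given for it the cause was not tested. Thinning, which tested the number of counts sampled, gave 1143, 2050, 75 and 699 calls at 40 mg/kg/day in liver mRNA, placenta mRNA, liver small RNA and placenta small RNA. Of simulated 1.5 fold changes 10.4% or fewer were recovered in liver mRNA and both small RNA datasets, and the cause was not tested.

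Leaving out low or missing RIN gave 4667 liver genes at 20 mg/kg/day, 4915 at the lower doses, 181 liver small RNA features at 20, and median response doses of 2.04 (liver mRNA) and 1.01 mg/kg/day (liver small RNA). limma voom gave 4217 and 5607 liver genes at 20 and the lower doses, 1061 and 2251 placental genes, and 212 placental small RNA features at the lower doses. The DESeq2 Wald test gave 719 and 83 placental genes at 20 and the lower doses, 134 liver small RNA features at 40 and 211 placental ones at the lower doses, where DESeq2 size factors gave 90. Without a filter 4 placental genes (lower doses) and 157 liver small RNA features (40) were called, and with edgeR's legacy dispersion 1 placental gene (lower doses). A minimum of 1.5 fold left 1348, 278 and 1152 placental genes at 40, at 20 and in the trend, by its construction. A benchmark of 1.5 fold moved the median response dose to 10.8 (placenta mRNA), 3.35 (liver small RNA) and 12.6 mg/kg/day (placenta small RNA).

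With RIN as a covariate over libraries of RIN 7 or more, liver genes at 40, 20, the lower doses and in the trend numbered 135, 718, 1928 and 1641, with the integrity score 675, 376, 93 and 693, and with the score over RIN 7 or more 23, 4, 600 and 67. That score is made from expression, so it also removes any response to dose in the same genes. Placental genes at 20 and the lower doses numbered 707 and 1 with RIN as a covariate, 736 and 5 over RIN 7 or more, and 851 and 44 with the abundant-gene share; thinning left 0 at the lower doses. Libraries over 12 M counts gave 121 and 107 liver small RNA features at 40 and the lower doses, the latter with 1 library left at 6.3 mg/kg/day (101 calls) and none at 2, and that lone library is assumed to vary like the other groups. The depth class as a covariate gave 144 and 349, and log2 of the total counts 111, 180 and 167 at 40, 20 and the lower doses, with 1 placental gene at the lower doses.

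For the mRNA interaction, 134 calls became 5 with the dam as a replicate block, 497 without dams of low RIN and 86 without a filter. The paired fit, run for both interactions, gave 217 calls in small RNA, 199 of them among the 230 of the unpaired fit.

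Leaving out 1 library at a time, liver mRNA counts ranged from 344 to 2623 at 40 mg/kg/day, 724 to 4439 at 20 and 1408 to 4988 at the lower doses, and placental ones from 176 to 563 at 20 and 1 to 73 at the lower doses. Liver small RNA counts ranged from 6 to 120 at 40 and 158 to 270 at 20. Placental small RNA counts ranged from 375 to 902 at 40, 80 to 335 at 20, 20 to 161 at the lower doses and 737 to 1308 in the trend. The mRNA interaction ranged from 3 to 171 without 1 dam. Without 1 vehicle library the median response dose ranged from 2.93 to 3.69 mg/kg/day in liver mRNA and 5.37 to 7.29 in placenta mRNA.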

Other observations

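Across the 4740 features tested in both placental tables, 86 were called at 40 mg/kg/day in mRNA and small RNA, 65 of them in the same direction, where independent lists give 74.9 and 39.0. In liver 12 of 4454 were called in both, all 12 in the same direction, where independent lists give 2.65 and 1.43. The libraries come from the same dams.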
